A study of Mus musculus with 15 samples.

How the data were processed

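RNA was sequenced from primary mouse ovarian granulosa cells, the somatic cells that surround and feed the oocyte, taken from 8-week-old SWISS females. Per the labels, the cells grew in 6-well plates and were transfected with 30 pmol of siRNA using a lipid reagent, and each target was hit by pools of 3 siRNAs, with 4 pools named per target. The labels list the same siRNA catalogue numbers for both targets, so which siRNAs made up each pool is not known here. Libraries were made from 1.3 µg of RNA with a stranded poly(A) mRNA kit and ERCC spike-in RNA, and read as single 75-base reads. The sample titles put the 15 libraries into 5 groups of 3: scrambled siRNA at 30 h and at 54 h after transfection, Foxl2 siRNA at 30 h and at 54 h, and Esr2 siRNA at 30 h. The extract protocol names 30 h as the time of extraction and does not mention 54 h; the times used here are those of the titles. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, nor which siRNA pool went into which library, so p-values measure only the spread between these libraries, which may be partly technical.

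The deposited values are whole-number counts of reads per gene for each library, not normalized, as the authors made them. The submitters' processing notes name bcl2fastq 2.15.0, TopHat2, DESeq2 and the mouse build mm10; the counting program, its annotation and its strand setting are not given in the sources used here. Each library had values for 24582 features, of which 92 were ERCC spike-ins and 24490 were genes, and 3983 genes had a count of 0 in all 15 libraries. In 1 scrambled library at 30 h, 15 gene symbols had been turned into dates, as spreadsheet programs do, and were restored by their place in the gene order that the other libraries share. A deposited table of the whole series was used only as a check: it had 45 empty cells, 15 for each Esr2 siRNA library, and 0 of the remaining cells differed from the counts of the single libraries. Spike-ins were left out of library sizes and tests and made up 0.105% to 0.352% of all counts of a library.

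Gene counts per library ranged from 45.0 M to 59.6 M, with a median of 52.4 M, and 17404 to 17831 genes had at least 1 count. The 10 most abundant genes took 4.37% to 6.44% of a library. A gene with a count of 0 could still lie at up to 0.0504 to 0.0667 counts-per-million (CPM), the value of 3 counts in the deepest and the shallowest library; this floor and the 95% exact intervals given for ratios of low counts cover counting error only. Replicates differed by far more than sampling noise in every group: the chi-square statistic per degree of freedom over genes lay between 7.18 and 129, so no library was a copy of another.

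Differences were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over the 14907 genes kept by its expression filter and with TMM scaling. All 15 libraries entered 1 fit of 5 group means, with 10 residual degrees of freedom, a common dispersion of 0.022 and a biological coefficient of variation of 0.15. A gene was called at an adjusted p under 0.05. The contrasts were Foxl2 siRNA against scrambled at 30 h and at 54 h, Esr2 siRNA against scrambled at 30 h, scrambled at 54 h against 30 h, the difference between the Foxl2 siRNA changes at 54 h and 30 h, and Foxl2 siRNA against Esr2 siRNA at 30 h. Log2 fold changes are given with the standard error derived from the quasi-likelihood F statistic, and levels as TMM-normalised CPM with the mean and SD of 3 libraries. A rank or permutation test of 3 against 3 libraries cannot go below p = 0.1, so single levels were not tested that way.

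Gene lists were fixed before the data were examined, as were the groups, the tests, the rule for named genes and all alternatives except those named below. The 32 lists held 1015 genes: granulosa identity, Sertoli and testis genes, steroidogenesis, cholesterol synthesis, TGF-beta with BMP and activin, Wnt, Notch, structural extracellular matrix, integrins and focal adhesion, cell-cell junctions, invasion proteases, migration and guidance, epithelial-mesenchymal transition, actomyosin, cell cycle, p53 and apoptosis, unfolded protein and integrated stress response, interferon response, inflammatory cytokines, ovulation and cumulus, luteal genes, oestrogen-responsive genes, glycolysis and hypoxia, DNA repair, dissociation stress, and markers of theca and stroma, leukocytes, endothelium, oocyte, surface epithelium, smooth muscle with pericytes, and erythroid cells. The 31 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera compares the genes of a list with all other genes. Fry, run beside it, tests whether the genes of a list move on balance in 1 direction, and its mixed form whether they change in either direction; neither compares the list with other genes. For each list the calls over all genes are given beside the calls with p-values adjusted over the list alone. No list call in any comparison held when camera estimated the correlation between genes, and the p-value of that fit is given beside the calls. A list score per library is the mean over its members of log2 CPM minus the mean of the scrambled libraries at 30 h.

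Genes are named by this rule: the targets Foxl2 and Esr2; a panel of genes (Esr1, Sox9, Dmrt1, Cyp19a1, Fst, Star, Amh, Fshr, Pgr, Nr5a2 and Inha); the 10 called genes with the largest rise and the 10 with the largest fall in each comparison with scrambled siRNA and between the scrambled times, and 5 and 5 in the other 2 comparisons, among genes with a mean log2 CPM of at least 2 and no overlap between the 3 libraries of either group; and up to 4 members with the smallest p-value of each list described. Predicted genes and pseudogenes are not named, some genes that the rule takes are not reported here, and Dmrt1 was not among the tested genes. Positions are from the GENCODE M21 annotation of GRCm38, which is mm10. Of the 188 named genes, 184 were found by symbol and 4 by a newer name; 20 that overlap another gene or share at least 10% of their 75-base words with one are uncertain, because the strand setting of the counting is not known.

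Whether replicate numbers pair libraries was checked on the correlation across genes of same-numbered libraries' deviations from their group means. For scrambled siRNA at 30 h and 54 h it was 0.63, 0.49 and 0.14 for numbers 1, 2 and 3, each over 0.1. These were taken as pairs in the fits with a replicate block, while the main fit used no pairs. The pairing comes from the data, not from the labels, and is weak for number 3. Scrambled replicate 3 at 30 h correlated at 0.34 with scrambled replicate 2 at 54 h. The 2 knockdowns at 30 h share 3 scrambled libraries. For this, 20 simulated sets of unchanged groups against those libraries give the overlap where neither siRNA changes a gene.

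Alternatives were DESeq2's size factors and upper-quartile factors in the edgeR fit, no filter on low counts, a stricter filter (CPM of at least 1 in at least 3 libraries), DESeq2 1.42.0, limma voom with sample quality weights, the replicate number as a block, only the groups compared, a 2-fold minimum, an adjusted p under 0.01, each library left out in turn, and for lists an estimated correlation and fry. Chosen after seeing the data were a theca and stroma score as a covariate, a fit of the 6 scrambled libraries alone with the replicate block, a fit without the 2 Foxl2 siRNA libraries that kept most Foxl2, and leaving out each library and the replicate block for the lists of the last 2 contrasts. The edgeR fit was tested on simulated data of 14907 genes with 200 changed. For Foxl2 siRNA at 30 h it recovered 38.8%, 73.1% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold, with 10 false among 145 calls, and for Esr2 siRNA 44.8%, 77.6% and 92.4%, with 2 false among 145 calls. In the same simulations DESeq2 made 44 and 36 false calls and voom 10 and 4. All simulated groups had the same spread per gene and genes varied independently. These rates need not hold where the real groups differ in spread.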

Results

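The study asked which genes depend on FOXL2 and ESR2 in cultured mouse granulosa cells, with cell migration, invasion and adhesion as the processes of interest. FOXL2 is a forkhead transcription factor that keeps granulosa cells in their female identity, and ESR2 is the oestrogen receptor beta. Poly(A) RNA was sequenced from 15 libraries in 5 groups of 3: scrambled siRNA at 30 h and 54 h, Foxl2 siRNA at 30 h and 54 h, and Esr2 siRNA at 30 h. Gene counts in replicates 1 to 3 were 52411259, 44976872 and 59436383 with scrambled siRNA at 30 h and 54118121, 52139885 and 56889581 at 54 h. They were 58124782, 51100555 and 55664044 after Esr2 siRNA. Foxl2 siRNA gave 50690877, 51304984 and 50687790 at 30 h and 47647007, 59550065 and 53994730 at 54 h. Principal component 1 of log2 CPM held 49.4% of the variance and separated Foxl2 siRNA from the other groups. Its scores were 33.1, 34 and 6.2 in Foxl2 siRNA replicates 1 to 3 at 30 h and 73, 32.4 and 63 at 54 h, against -21.7 to -32.4 in all scrambled and Esr2 siRNA libraries. Components 2 and 3 held 15.5% and 10.9%. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Log2 changes are given ± their standard error, with 3 libraries per group.

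Each siRNA lowered its target in every library. Foxl2 (mm10 chromosome 9, 98955288 to 98958543, plus strand) stood at 174, 152 and 143 CPM in scrambled replicates 1 to 3 at 30 h and at 33.8, 28.4 and 65.4 CPM after Foxl2 siRNA. This fall was 3.68-fold (log2 -1.88 ± 0.31, edgeR adjusted p = 0.00164). At 54 h it was 189, 154 and 166 CPM with scrambled siRNA and 33.7, 57.5 and 25.2 CPM with Foxl2 siRNA, 4.36-fold lower (log2 -2.13 ± 0.31, edgeR adjusted p = 0.000191). Esr2 (chromosome 12, 76120419 to 76177259, minus strand) fell 4.43-fold after Esr2 siRNA, from 60.6, 60.4 and 61.6 CPM to 12.9, 14.5 and 13.9 CPM (log2 -2.15 ± 0.35, edgeR adjusted p = 0.00375). Foxl2 siRNA replicate 3 at 30 h and replicate 2 at 54 h kept the most Foxl2 of their groups, and the same libraries kept the most Esr2. Esr2 stood at 45.5 CPM in the former against 29.2 and 25.0 CPM in its group, and at 49.3 CPM in the latter against 18.0 and 15.7 CPM. Esr2 fell 2.48-fold after Foxl2 siRNA at 54 h (log2 -1.31 ± 0.34, edgeR adjusted p = 0.00854), a call lost when only the groups compared were fitted (0.0652). Without Foxl2 siRNA replicate 2 at 54 h its log2 change was -2.03. Its change at 30 h did not pass (log2 -0.87 ± 0.34, edgeR adjusted p = 0.109). Foxl2 stood at 112, 128 and 114 CPM after Esr2 siRNA, a log2 change of -0.41 ± 0.29 that did not pass (edgeR adjusted p = 0.539). These libraries did not overlap the scrambled ones at 30 h. The fit takes the spread of a gene from all 15 libraries, and Foxl2 ran from 25.2 to 65.4 CPM over the Foxl2 siRNA libraries. A fall of Foxl2 after Esr2 siRNA is therefore not excluded.

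**Figure D1:**
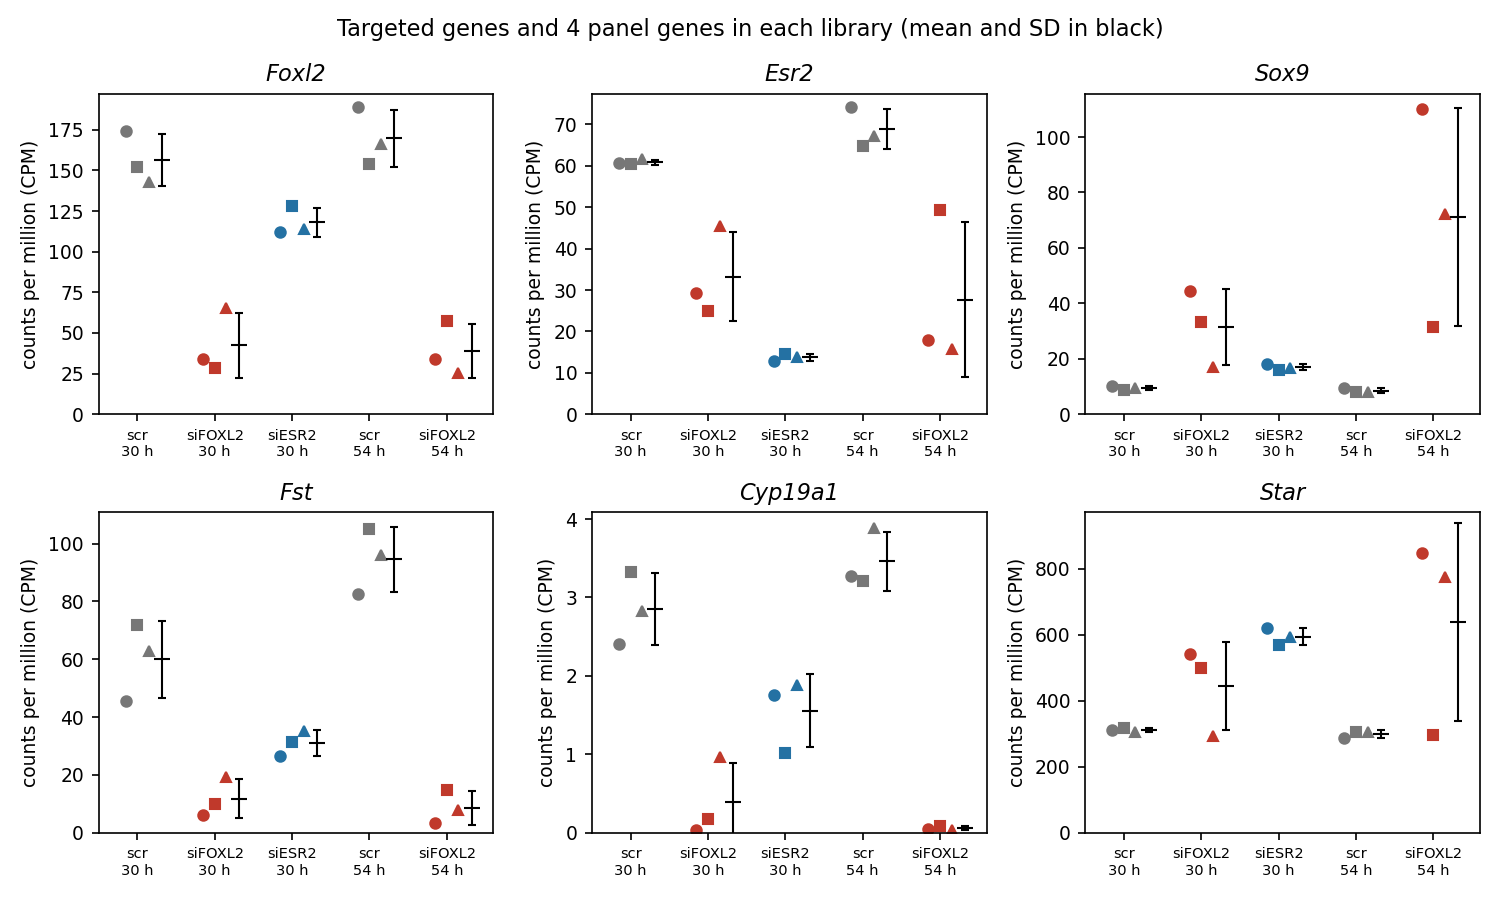
Normalised level (CPM, y axis) of Foxl2, Esr2, Sox9, Fst, Cyp19a1 and Star in the 5 groups (x axis), with replicates 1, 2 and 3 as circles, squares and triangles and the mean ± SD of 3 libraries in black. Foxl2 averaged 42.5 ± 20 CPM after Foxl2 siRNA at 30 h and 38.8 ± 16.7 CPM at 54 h, against 157 ± 16.1 and 169 ± 17.6 CPM with scrambled siRNA.

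At 30 h, Foxl2 siRNA lowered the granulosa genes Fst and Cyp19a1 and raised the testis genes Sox9 and Sox8. Fst, which encodes the activin antagonist follistatin (chromosome 13, 114452290 to 114458951, minus strand), fell 5.07-fold from 60 to 11.8 CPM (log2 -2.34 ± 0.45, edgeR adjusted p = 0.00486), and voom gave a log2 change of -2.97. Cyp19a1, which encodes the oestrogen-making enzyme aromatase (chromosome 9, 54165937 to 54268110, minus strand), fell from 2.86 to 0.394 CPM (log2 -2.84 ± 0.61, edgeR adjusted p = 0.00898). Its 446 counts with scrambled siRNA against 60 gave a ratio of 7.13 with a 95% exact interval of 5.44 to 9.5, and the call was lost when only the groups compared were fitted (0.0647). The log2 change of Cyp19a1 was -4.68 without Foxl2 siRNA replicate 3 and -4.88 with voom. Sox9, a driver of Sertoli cell formation (chromosome 11, 112782224 to 112787760, plus strand), rose 3.33-fold from 9.44 to 31.4 CPM (log2 1.73 ± 0.38, edgeR adjusted p = 0.0109). Without Foxl2 siRNA replicate 1 its adjusted p was 0.0506. Sox8, a relative of Sox9, rose 2.86-fold from 9 to 25.8 CPM (log2 1.52 ± 0.18, edgeR adjusted p = 0.000265). No other gene named from the panel passed. The log2 changes were 0.52 ± 0.30 for Star, 0.22 ± 0.52 for Amh, 0.73 ± 0.47 for Fshr and -0.39 for Pgr. They were -0.10 for Esr1, -0.15 for Nr5a2 and 0.01 for Inha. Adjusted p-values of these genes ran from 0.284 for Star to 0.973 for Inha, and Dmrt1 was not among the tested genes.

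Among the genes named by rule at 30 h was Asb12 (chromosome X, 95470201 to 95557987, minus strand), which rose 6.42-fold from 5.04 to 32.4 CPM (log2 2.68 ± 0.20, edgeR adjusted p = 1.56e-05). Ryr2, the calcium release channel of heart muscle, rose 4.88-fold (log2 2.29 ± 0.22). Mybpc3, cardiac myosin-binding protein C (chromosome 2, 91118144 to 91136516, plus strand), rose 4.24-fold from 24 to 102 CPM (log2 2.09 ± 0.28, edgeR adjusted p = 0.000529). The guidance receptor genes Robo4 and Plxna4 rose 5.19-fold and 4.05-fold, and Serpina3a and Mybphl 8.01-fold and 8.51-fold. Gpr165 fell 14.8-fold from 22 to 1.48 CPM (log2 -3.88 ± 0.58), and Slc16a11, a monocarboxylate transporter gene, 8.98-fold from 71 to 7.91 CPM (log2 -3.17 ± 0.44). Asgr1, Rnf152 and Cdo1 fell 8.45-fold, 7.48-fold and 7.45-fold. The matrix gene Frem2 and the teneurin gene Tenm4 fell 8.02-fold and 6.94-fold. Kif26b, Nat8l and Grem1 were also among them (log2 2.92 ± 0.65, 2.46 ± 0.75 and -2.93 ± 0.77), but each of these calls was lost when any 1 of several libraries was left out. The adjusted p of Kif26b was 0.054 without scrambled replicate 1 and 0.0553 without replicate 3. Without scrambled replicate 1, 2 or 3 or Foxl2 siRNA replicate 1 or 2, it was 0.107 to 0.178 for Nat8l and 0.0524 to 0.0998 for Grem1. Without Foxl2 siRNA replicate 3 the log2 changes of Gpr165, Slc16a11 and Grem1 were -4.64, -3.75 and -3.78, and without replicate 1 that of Nat8l was 1.85. Voom gave -3.56 for Grem1 and -3.44 for Tenm4.

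No list tied to adhesion, migration or invasion passed camera at 30 h, yet each held genes that rose and genes that fell. Among 47 integrin and focal adhesion genes 9 rose and 4 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.0675). The focal adhesion adaptor gene Bcar1 rose 1.47-fold from 211 to 310 CPM (log2 0.56 ± 0.06, edgeR adjusted p = 0.000108), and Zyx rose 1.47-fold too. Itga2, a collagen-binding integrin subunit, fell 5.81-fold from 64.9 to 11.2 CPM (log2 -2.54 ± 0.34), and Itgb5 1.64-fold from 860 to 526 CPM. Of 46 cell-cell junction genes 7 rose and 7 fell (14 and 7 adjusted over the list alone, camera adjusted p = 0.133). Cdh3, which encodes P-cadherin, rose 2.31-fold from 34.4 to 79.6 CPM, and the protocadherin gene Pcdh18 fell 3.41-fold from 47.5 to 13.9 CPM. Of 58 migration and guidance genes 8 rose and 6 fell (12 and 9 adjusted over the list alone, camera adjusted p = 0.371). Efnb1 rose 2.4-fold from 50.7 to 122 CPM. Robo2, a Slit receptor gene (chromosome 16, 73891839 to 74411825, minus strand), fell 2.31-fold from 331 to 144 CPM (log2 -1.21 ± 0.14, edgeR adjusted p = 0.000265). Among 58 structural matrix genes 3 rose and 4 fell (3 and 4 adjusted over the list alone). Camera put them upward (adjusted p = 0.712) although the mean log2 change was -0.04. The basement membrane collagen genes Col4a5 and Col4a6 rose 1.64-fold and 1.86-fold, and Lama1 and Spp1 fell 2.32-fold and 2.37-fold. Of 52 invasion proteases and inhibitors 6 rose and 5 fell (6 and 8 adjusted over the list alone, camera adjusted p = 0.95). Adamts1 rose 1.68-fold, and Plat, tissue plasminogen activator, fell (log2 -0.48 ± 0.09, edgeR adjusted p = 0.0044).

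Member counts of these lists moved with single libraries. Junction genes higher and lower were 4 and 2 without scrambled replicate 1, 2 or 3 or Foxl2 siRNA replicate 1 or 2, and 13 were higher without Foxl2 siRNA replicate 3. Integrin genes higher were 5 without scrambled replicate 3 or Foxl2 siRNA replicate 2. Migration genes higher were 5 without scrambled replicate 3 and 13 without Foxl2 siRNA replicate 3. Matrix genes lower were 2 without scrambled replicate 1, 2 or 3 or Foxl2 siRNA replicate 1, and 6 were higher without Foxl2 siRNA replicate 3. Protease genes higher were 3 without scrambled replicate 1 or Foxl2 siRNA replicate 2. Protease genes lower were 3, 3 and 2 without scrambled replicates 1, 2 and 3, and 1 and 2 without Foxl2 siRNA replicates 1 and 2.

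Camera called 7 of 31 lists at 30 h, 5 upward and 2 downward. Sertoli and testis genes moved upward, with 4 of 20 called higher and 0 lower (8 and 0 adjusted over the list alone) and a median of 0.69 (camera adjusted p = 0.00122). Cholesterol synthesis moved upward, with 6 of 25 higher and 1 lower (10 and 1 adjusted over the list alone, camera adjusted p = 0.00122). Sc5d, a late enzyme of that pathway, fell 1.8-fold from 260 to 145 CPM (log2 -0.85 ± 0.07, edgeR adjusted p = 3.64e-05). Ovulation and cumulus genes moved downward, with 2 of 27 higher and 8 lower (2 and 10 adjusted over the list alone, camera adjusted p = 0.00234). Ptger2, a prostaglandin receptor gene, fell 3.12-fold from 61.8 to 19.8 CPM, the growth factor gene Btc 3.46-fold and Rgs2 3.07-fold. The cell cycle list moved downward with a median of -0.25 and 1 of 50 genes called lower (0 adjusted over the list alone, camera adjusted p = 5.23e-05). The p53 and apoptosis list moved upward with 6 of 35 called higher (7 adjusted over the list alone, camera adjusted p = 0.0165), among them Gadd45b, 1.68-fold from 29.2 to 49.2 CPM. Interferon response genes had a median of 0.33 with 1 of 39 called higher (1 adjusted over the list alone, camera adjusted p = 0.0312). Markers of another cell type, the ovarian surface epithelium, moved upward in the same group: 5 of 17 were higher (8 adjusted over the list alone, camera adjusted p = 0.00184). Their score was 0.29, 0.68 and 0.57 in Foxl2 siRNA replicates 1 to 3, where the Sertoli score was 1.01, 0.73 and 0.52. Msln rose 2.72-fold from 13.2 to 35.8 CPM and Wt1 1.96-fold from 96.4 to 189 CPM. No list was called with an estimated correlation. The adjusted p was 0.709 for Sertoli, ovulation and surface epithelium genes, 0.812 for cholesterol and p53 genes, 0.814 for the cell cycle and 0.873 for interferon genes with an estimated correlation.

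Fry called Sertoli genes upward at 30 h (adjusted p = 0.0242), and ovulation (0.0226) and granulosa identity genes (0.00494) downward. Camera did not call granulosa identity genes (adjusted p = 0.202), of which 3 of 24 rose and 4 fell (3 and 9 adjusted over the list alone). Steroidogenic genes went both ways, 3 of 21 higher and 3 lower (4 and 5 adjusted over the list alone), and camera put them downward (adjusted p = 0.95) although their median was 0.09. Cyp11a1, the side-chain cleavage enzyme, rose 1.61-fold from 2530 to 4060 CPM, and Hsd11b2, which inactivates glucocorticoids, fell 3.66-fold from 22.9 to 6.25 CPM. Single libraries decided some list calls. The interferon list was lost without scrambled replicate 2 (0.0871) and without Foxl2 siRNA replicates 2 (0.355) and 3 (0.339). The p53 list was lost without Foxl2 siRNA replicates 1 (0.0728) and 3 (0.0759), and the ovulation list without replicate 3 (0.0759). Cholesterol genes higher were 3, 3 and 2 without scrambled replicates 1, 2 and 3 and 2, 3 and 13 without Foxl2 siRNA replicates 1, 2 and 3. Without Foxl2 siRNA replicate 3, 7 Sertoli genes were higher and 13 cell cycle, 8 granulosa and 7 steroidogenic genes lower. The p53 genes higher were 3 without scrambled replicate 3. Ovulation genes lower were 5 without scrambled replicate 2 or 3 or Foxl2 siRNA replicate 1, and granulosa genes lower were 2 without scrambled replicate 1, 2 or 3.

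Over all 14907 tested genes 1936 (13%) were called at 30 h, 945 higher and 991 lower. Of these 235 and 269 changed at least 2-fold, and 4191 genes had an unadjusted p under 0.05. The count was 1073, 1171 and 898 without scrambled replicates 1, 2 and 3, and 1061, 1085 and 3016 without Foxl2 siRNA replicates 1, 2 and 3. With upper-quartile scaling the split was 1204 higher and 799 lower, and voom with quality weights called 5252 genes.

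At 54 h, Foxl2 siRNA again raised Sox9 and lowered Fst and Cyp19a1. Sox9 rose 8.37-fold from 8.51 to 71.4 CPM (log2 3.07 ± 0.40, edgeR adjusted p = 8.91e-05), with 110, 31.4 and 72.3 CPM in replicates 1 to 3. Fst fell 10.8-fold from 94.4 to 8.67 CPM (log2 -3.43 ± 0.47, edgeR adjusted p = 0.000129), and its log2 change was -4.06 without Foxl2 siRNA replicate 2. Cyp19a1 was close to the counting floor of 0.0504 to 0.0667 CPM after Foxl2 siRNA, with 9 counts over 3 libraries against 573. The ratio was 60.4 with a 95% exact interval of 31.6 to 133 (edgeR adjusted p = 0.000104). Star, which moves cholesterol into mitochondria for steroid synthesis (chromosome 8, 25806555 to 25815982, plus strand), rose 2.14-fold from 299 to 639 CPM (log2 1.09 ± 0.30, edgeR adjusted p = 0.0115). That call was lost without Foxl2 siRNA replicate 1 (0.0589) and when only the groups compared were fitted (0.0632). Nr5a2, a nuclear receptor gene of granulosa cells, fell 1.58-fold. Amh, which encodes the anti-Muellerian hormone, rose 3.6-fold at a low level, from 0.29 to 1.06 CPM (log2 1.85 ± 0.47, edgeR adjusted p = 0.00722), with a log2 change of 1.17 without Foxl2 siRNA replicate 1. Esr1, Fshr, Inha and Pgr did not pass, with log2 changes of -0.14, 0.04, -0.15 and -0.31 and edgeR adjusted p-values of 0.665, 0.953, 0.533 and 0.749. The LH receptor gene Lhcgr fell by 3.39 on the log2 scale (edgeR adjusted p = 1.17e-05), with 125 counts against 11, a ratio of 10.8 with an interval of 5.82 to 22.2.

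Among the genes named by rule, Serpina3a rose 37.3-fold at 54 h, from 0.726 to 27.2 CPM, and Mybphl 24.5-fold from 1.07 to 26.3 CPM. Mybpc3 rose 12.2-fold from 24.7 to 302 CPM (log2 3.61 ± 0.30, edgeR adjusted p = 3.18e-06) and Asb12 11.1-fold from 4.71 to 52.1 CPM (log2 3.47 ± 0.20, edgeR adjusted p = 4.05e-07). Kif26b, Nat8l, Robo4, Lrrn4 and Nkain3 rose 20-fold, 17.1-fold, 11.3-fold, 11.2-fold and 9.84-fold. Gpr165 fell 34.3-fold from 39.6 to 1.11 CPM and Slc16a11 28.6-fold from 92.7 to 3.17 CPM. The amino acid transporter gene Slc7a8 (chromosome 14, 54722209 to 54781946, minus strand) fell 15.5-fold from 504 to 32.3 CPM (log2 -3.96 ± 0.35, edgeR adjusted p = 5.29e-06). The BMP antagonist gene Grem1 fell 18.1-fold and the chemokine gene Cxcl13 20.2-fold. Asgr1, Nap1l5 and Rnf152 fell 22.2-fold, 21-fold and 12.6-fold, and Lypd6 by 3.69 ± 0.52 on the log2 scale. Without Foxl2 siRNA replicate 2 the log2 changes were -6.41 for Gpr165, -5.84 for Slc16a11, -6.35 for Grem1, -5.16 for Asgr1 and -4.36 for Lypd6. Without replicate 1 they were 3.95 for Mybphl and 3.17 for Nat8l, and voom gave -6.09, -5.60 and -5.98 for Gpr165, Slc16a11 and Grem1. In all, 5787 genes (38.8%) were called, 2755 higher and 3032 lower. Of these 887 and 643 changed at least 2-fold, and 7057 genes had an unadjusted p under 0.05.

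**Figure D2:**
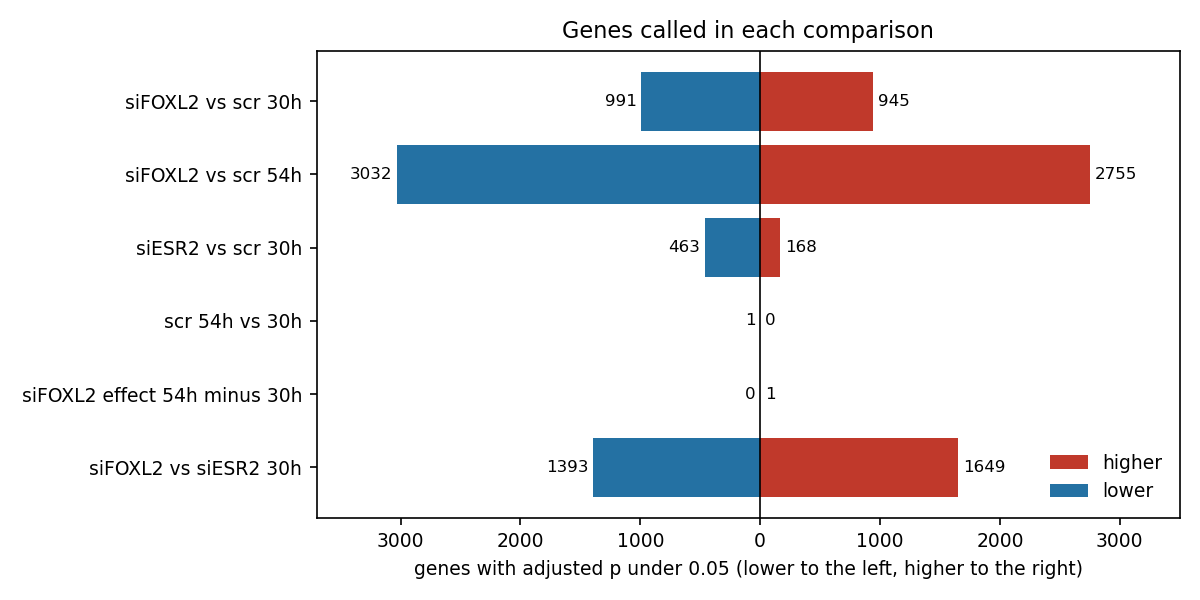
Number of genes called in each comparison (x axis, genes with adjusted p under 0.05 among 14907 tested), with bars to the left for lower and to the right for higher genes. Foxl2 siRNA gave 991 lower and 945 higher genes at 30 h (799 and 1204 with upper-quartile scaling) and 3032 lower and 2755 higher at 54 h, and Esr2 siRNA 463 lower and 168 higher (396 and 250 with upper-quartile scaling).

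Adhesion and cytoskeleton genes moved upward as lists at 54 h. Of 47 integrin and focal adhesion genes 23 rose and 6 fell (23 and 6 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.000593; adjusted p = 0.362 with an estimated correlation). Bcar1 rose 2.14-fold from 156 to 333 CPM (log2 1.10 ± 0.06, edgeR adjusted p = 1.67e-07), Zyx 1.92-fold and Sorbs3 by a log2 of 0.95 ± 0.09, while Itga2 fell 8.34-fold from 92.6 to 11 CPM. Of 37 actomyosin genes 18 rose and 0 fell (19 and 0 adjusted over the list alone, camera adjusted p = 8.44e-05; adjusted p = 0.348 with an estimated correlation). The list's score was -0.27 ± 0.28 with scrambled siRNA and 0.05 ± 0.21 with Foxl2 siRNA at 54 h, relative to scrambled cells at 30 h (SD, n = 3). The myosin light chain gene Myl9 rose 2.03-fold, and the YAP target genes Ctgf and Cyr61 rose 3.17-fold, from 473 to 1500 CPM, and 2.3-fold. After Foxl2 siRNA Cyr61 was no higher at 54 h (513, 611 and 528 CPM) than at 30 h (534, 629 and 531 CPM), unlike Ctgf. With scrambled siRNA Cyr61 stood at 436, 354 and 370 CPM at 30 h and at 222, 256 and 242 CPM at 54 h. Scrambled levels of Bcar1 were also lower at 54 h (156, 157 and 154 CPM) than at 30 h (227, 198 and 208 CPM). Of 46 cell-cell junction genes 18 rose and 9 fell (21 and 9 adjusted over the list alone, camera adjusted p = 0.0309; adjusted p = 0.317 with an estimated correlation). Cdh3 rose 3.34-fold and Pcdh18 fell 5.6-fold. Gja1, which encodes the gap junction protein connexin 43 (chromosome 10, 56377330 to 56402513, plus strand), stood at 80.5, 375 and 119 CPM in replicates 1 to 3 against 1620, 1700 and 1650 CPM with scrambled siRNA.

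The structural matrix, migration, protease and epithelial-mesenchymal transition lists did not pass at 54 h. Matrix genes had 19 of 58 higher and 8 lower (19 and 8 adjusted over the list alone, camera adjusted p = 0.175), and 9 higher without scrambled replicate 1. Col4a5 rose 2.21-fold from 461 to 1020 CPM and Sparc 1.89-fold, and Spp1 fell 6.3-fold from 625 to 99.2 CPM. Migration and guidance genes had 20 of 58 higher and 11 lower (20 and 11 adjusted over the list alone, camera adjusted p = 0.462). Robo2 fell 5.65-fold from 342 to 60.6 CPM (log2 -2.50 ± 0.15, edgeR adjusted p = 4.18e-07), Robo1 fell 2.62-fold and Efnb1 rose 2.99-fold. Invasion proteases had 11 of 52 higher and 9 lower (11 and 9 adjusted over the list alone), and camera put them upward (adjusted p = 0.543) with a mean of -0.04. The metalloproteinase inhibitor gene Timp2 rose 1.67-fold from 458 to 763 CPM and the urokinase receptor gene Plaur 2.29-fold, and the heparanase gene Hpse fell 4.07-fold. Epithelial-mesenchymal transition genes had 5 of 27 higher and 3 lower (5 and 3 adjusted over the list alone, camera adjusted p = 0.417).

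Cell cycle genes fell as a list at 54 h: 48 of 50 were lower and 0 higher (49 and 0 adjusted over the list alone), with a median of -0.76. The camera adjusted p was 6.77e-15, and the adjusted p = 0.467 with an estimated correlation. E2f8, Cdc45 and Tyms, genes of DNA replication, fell 2.26-fold, 2-fold and 1.95-fold. DNA repair genes had 25 of 40 lower and 0 higher (26 and 0 adjusted over the list alone, camera adjusted p = 1.57e-05; adjusted p = 0.374 with an estimated correlation), and Exo1 fell 2.19-fold. The p53 and apoptosis list had 20 of 35 higher and 1 lower (21 and 1 adjusted over the list alone, camera adjusted p = 1.26e-05; adjusted p = 0.317 with an estimated correlation). The death-promoting gene Bik rose 5.68-fold, and Gadd45b (chromosome 10, 80930073 to 80932204, plus strand) 3.58-fold from 22.8 to 81.6 CPM. Ovulation and cumulus genes had 15 of 27 lower and 3 higher (16 and 3 adjusted over the list alone, camera adjusted p = 0.00133; adjusted p = 0.362 with an estimated correlation). Ptger2 fell 7.89-fold from 68.8 to 8.7 CPM, and the endothelin gene Edn2 rose 17.9-fold from 0.67 to 12.1 CPM.

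Sertoli and testis genes had 14 of 20 higher and 2 lower at 54 h (16 and 2 adjusted over the list alone), with a median of 1.34 (camera adjusted p = 7.45e-05; adjusted p = 0.317 with an estimated correlation). Gata1 rose 12.3-fold from 0.14 to 1.75 CPM, Cbln4 3.63-fold and Sox8 3.42-fold. The surface epithelium markers moved upward in the same group, 11 of 17 higher and 0 lower (12 and 0 adjusted over the list alone), with a median of 1.04 (camera adjusted p = 3.44e-05; adjusted p = 0.317 with an estimated correlation). Their score was 1.15, 1.57 and 1.22 in Foxl2 siRNA replicates 1 to 3, highest in replicate 2, where the Sertoli score (2.04, 1.08 and 1.38) was lowest. Msln rose 6.14-fold from 20.5 to 126 CPM and Wt1 2.76-fold from 108 to 298 CPM. Of these 17 markers, 7 exceeded 10 CPM in scrambled cells at 30 h and 4 are held by another list. The epithelial keratin gene Krt7, chosen after its values were seen, did not pass (log2 0.26 ± 0.62, edgeR adjusted p = 0.772).

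Interferon response genes had 13 of 39 higher and 0 lower at 54 h (12 and 0 adjusted over the list alone, camera adjusted p = 0.000981; adjusted p = 0.794 with an estimated correlation), and Ifit1 rose 3.22-fold. The count was 3, 6 and 6 without scrambled replicates 1, 2 and 3 and 2 without Foxl2 siRNA replicate 3. Glycolysis and hypoxia genes had 10 of 28 higher and 2 lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.0309; adjusted p = 0.548 with an estimated correlation), and Ddit4 rose 2.03-fold. Genes of the unfolded protein and integrated stress response had 13 of 28 lower and 3 higher (15 and 4 adjusted over the list alone, camera adjusted p = 0.0359; adjusted p = 0.548 with an estimated correlation). Among those that rose were the stress transcription factor genes Atf3, 3.28-fold, and Ddit3 (log2 0.67 ± 0.07). Cholesterol synthesis had 9 of 25 higher and 2 lower (12 and 3 adjusted over the list alone, camera adjusted p = 0.0359; adjusted p = 0.833 with an estimated correlation), and Sc5d fell 2.06-fold. Without Foxl2 siRNA replicate 2, 19 cholesterol genes were higher. Leaving out scrambled replicate 1 ended the camera calls of cholesterol (0.0963), junction (0.0671), stress response (0.0671) and glycolysis genes (0.0798). The cholesterol call also ended without Foxl2 siRNA replicates 1 (0.133) and 3 (0.183), the junction call without replicate 2 (0.0581) and the glycolysis call without replicate 3 (0.175). Camera called 13 of 31 lists, 9 upward and 4 downward.

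Granulosa identity genes had 5 of 24 higher and 10 lower at 54 h (5 and 10 adjusted over the list alone). Camera did not call them (adjusted p = 0.0947), and fry called them downward (adjusted p = 1.42e-05). Steroidogenic genes had 5 of 21 higher and 6 lower (5 and 6 adjusted over the list alone, camera adjusted p = 0.543). Hsd11b2 fell 5.3-fold and Hsd3b1, a progesterone-making enzyme, 2.19-fold from 2720 to 1240 CPM. Notch genes had 9 of 22 higher and 2 lower (9 and 2 adjusted over the list alone, camera adjusted p = 0.0582). Wnt genes had 9 of 35 higher and 7 lower (9 and 7 adjusted over the list alone, camera adjusted p = 0.597), and Rspo1 rose 8.75-fold from 0.591 to 5.19 CPM. The TGF-beta family had 8 of 42 higher and 11 lower (8 and 11 adjusted over the list alone, camera adjusted p = 0.612). Oestrogen-responsive genes had 5 of 27 higher and 8 lower (5 and 9 adjusted over the list alone, 0.506), and luteal genes 7 of 23 higher and 6 lower (8 and 6, 0.869). Inflammatory cytokines had 6 of 26 higher and 5 lower (6 and 5, 0.543), and dissociation stress genes 3 of 20 higher and 5 lower (3 and 5, 0.709). The TGF-beta genes higher were 5 without scrambled replicate 1, 2 or 3 or Foxl2 siRNA replicate 3 and 4 without Foxl2 siRNA replicate 1. Without that last library 3 steroidogenic and 4 luteal genes were higher, 11 Wnt genes were lower without replicate 2, and 4 Notch genes without replicate 3.

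Camera called no list of markers of the remaining cell types at 54 h, while fry called endothelial markers (median 0.52, adjusted p = 0.0421) and leukocyte markers (median 0.23, adjusted p = 0.0421) upward. Theca and stroma markers had 1 of 17 higher and 1 lower, and camera put them upward (adjusted p = 0.943) although the median was -0.17. Endothelial markers had 3 of 12 higher and 0 lower (camera adjusted p = 0.149), and leukocyte markers 2 of 6 higher and 1 lower (0.506). Smooth muscle and pericyte markers had 1 of 13 higher and 0 lower (0.543), and oocyte markers 1 of 5 higher and 1 lower (0.659). These counts were the same adjusted over the list alone. Of the 2 erythroid genes 1 was higher, a list too small to test. In scrambled cells at 30 h, 11 of the 17 theca and stroma and 8 of the 13 smooth muscle markers exceeded 10 CPM, against 0 of the leukocyte, endothelial, oocyte and erythroid markers. Another list holds 9 of the theca and stroma, 9 of the smooth muscle and 2 of the endothelial markers.

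**Figure D3:**
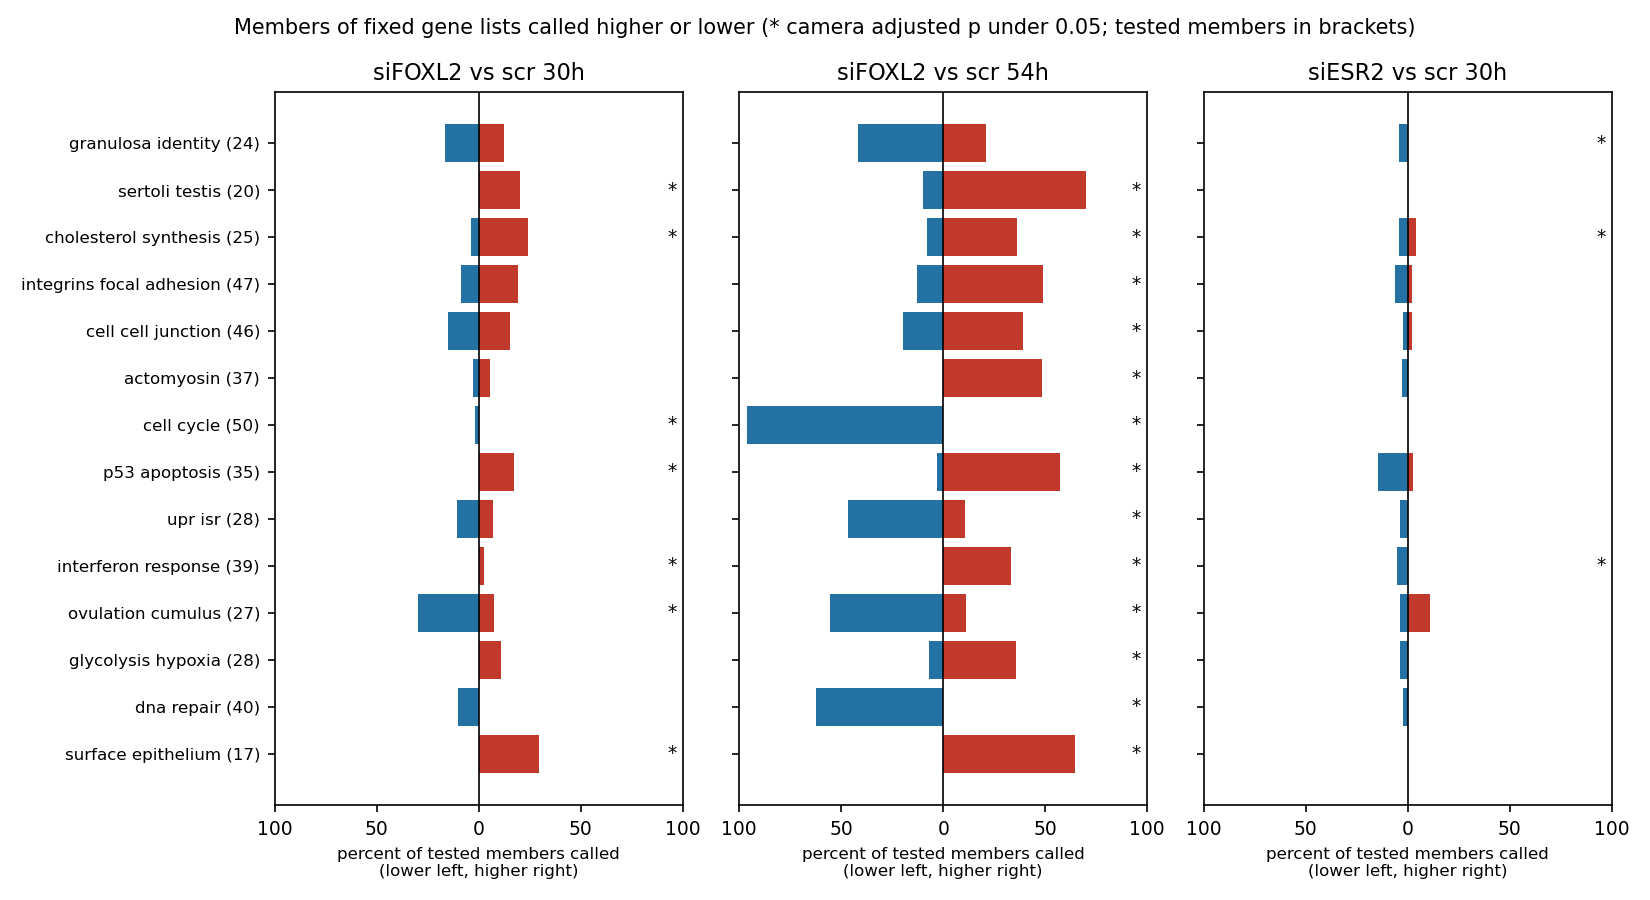
Percent of the tested members of each list (x axis; number tested in brackets) called lower (left) or higher (right) after Foxl2 siRNA at 30 h, Foxl2 siRNA at 54 h and Esr2 siRNA, with a star where camera gave an adjusted p under 0.05. At 54 h 48 of 50 cell cycle genes were lower and 14 of 20 Sertoli genes higher, and 0 of 50 and 0 of 20 were called after Esr2 siRNA.

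Whether the response to Foxl2 siRNA differed between the times was tested directly. Gadd45b, a stress-induced growth arrest gene, was the 1 gene called: its rise was larger at 54 h than at 30 h by 1.09 ± 0.12 on the log2 scale (edgeR adjusted p = 0.00778). It went from 45.4, 51.7 and 50.6 CPM to 86.5, 77.3 and 81.1 CPM after Foxl2 siRNA. With scrambled siRNA it went from 30.7, 29.2 and 27.7 CPM to 20.2, 25.4 and 22.8 CPM, so lower scrambled levels made up part of the difference. The test used no pairing of libraries across the times, and an unadjusted p under 0.05 was found for 1510 genes. For Foxl2 and Esr2 the difference was -0.24 ± 0.42 and -0.44 ± 0.47 (edgeR adjusted p = 0.92 and 0.84). Cell cycle genes as a list were lower in the later response (median -0.55, camera adjusted p = 4.37e-22), with 0 of 50 called and 1 lower adjusted over the list alone. Actomyosin genes were higher (median 0.39, camera adjusted p = 3.91e-12), with 0 of 37 called and 11 higher adjusted over the list alone. The actomyosin score was 0 ± 0.17 and -0.27 ± 0.28 with scrambled siRNA at 30 h and 54 h and -0.07 ± 0.25 and 0.05 ± 0.21 with Foxl2 siRNA (SD, n = 3), so the fall in the scrambled cells, which camera also called (adjusted p = 4.96e-12; adjusted p = 0.173 with an estimated correlation), made up part of the difference. Without Foxl2 siRNA 54 h replicate 2, 36 cell cycle genes were called lower and 7 actomyosin genes higher, and 1 cell cycle gene was lower without 30 h replicate 2. The adjusted p was 0.337 and 0.182 for these lists with an estimated correlation. The count of 1 gene depended on the libraries and the tool. It was 904 without Foxl2 siRNA 54 h replicate 2, 16 without 54 h replicate 3, 3 without 30 h replicate 2 and 2 without scrambled 54 h replicate 2. DESeq2 called 199 genes and voom 1056. Without both libraries that kept the most Foxl2, a fit chosen after seeing the data, 836 genes were called, 301 higher and 535 lower.

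The 30 h and 54 h calls shared 885 higher and 937 lower genes, against 174.6 and 201.6 for independent lists, and 0 genes went in opposite directions; Fst, Sox8 and Robo2 were among those shared. Log2 changes correlated at 0.86 across genes, which are not independent replicates. The shared total of 1822 fell to 1034, 1128 and 881 without scrambled 30 h replicates 1, 2 and 3, and to 1022 and 1047 without Foxl2 siRNA 30 h replicates 1 and 2.

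Esr2 siRNA at 30 h lowered more genes than it raised. Timp2, an inhibitor of matrix metalloproteinases (chromosome 11, 118301069 to 118355740, minus strand), fell 3.26-fold from 423 to 129 CPM (log2 -1.71 ± 0.09, edgeR adjusted p = 1.13e-06). Hsd11b2 (chromosome 8, 105518755 to 105523988, plus strand) fell 5.23-fold from 22.9 to 4.36 CPM (log2 -2.39 ± 0.22, edgeR adjusted p = 5.27e-05). The myelin protein gene Pmp22 fell 4.39-fold from 26.5 to 6.03 CPM (log2 -2.13 ± 0.21, edgeR adjusted p = 8.47e-05), Mctp1 6.45-fold from 9.66 to 1.49 CPM and Gpr165 9.99-fold from 22 to 2.19 CPM. Kcna4, a potassium channel gene, rose 2.3-fold (log2 1.20 ± 0.17, edgeR adjusted p = 0.00136), Tmtc1 2.14-fold and Plcxd2 1.88-fold. Btg2, an antiproliferative gene, rose 1.86-fold from 120 to 223 CPM. These calls, and those of Esr2, Sc5d, Col16a1, Plxna2, Plat and Lhcgr, stayed under 0.05 without any 1 library, as did 16 of the 41 named calls in all. Nppc, which encodes C-type natriuretic peptide, fell 4.64-fold (log2 -2.21 ± 0.53, edgeR adjusted p = 0.0333), and Cbs, an enzyme of cysteine synthesis, by 2.76 ± 0.72 on the log2 scale (0.0483). Both were lost without each of the 6 libraries, at 0.0722 to 0.127 for Nppc and 0.0888 to 0.2 for Cbs. Cbs was also lost with upper-quartile scaling (0.0521).

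No gene named from the panel passed after Esr2 siRNA. Star stood at 619, 568 and 593 CPM against 312, 316 and 305 CPM (log2 0.93 ± 0.30, edgeR adjusted p = 0.11). The fit takes the spread of a gene from all 15 libraries, and Star ran from 294 to 847 CPM over the Foxl2 siRNA libraries. Sox9 stood at 17 against 9.44 CPM (log2 0.85 ± 0.38, edgeR adjusted p = 0.27) and Fst at 31 against 60 CPM (log2 -0.95 ± 0.43, edgeR adjusted p = 0.27). For Star, Sox9 and Fst the Esr2 siRNA libraries did not overlap the scrambled ones. Cyp19a1 had a log2 change of -0.87 ± 0.54 (edgeR adjusted p = 0.453) and Nr5a2 of -0.42 ± 0.13 (0.0912). The adjusted p-values of Esr1, Fshr, Inha, Pgr and Amh ran from 0.717 to 0.89.

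In the adhesion and invasion lists Esr2 siRNA moved few genes. Of 52 invasion proteases and inhibitors 1 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.994). Fry's mixed test, for change in either direction, gave an adjusted p of 1.17e-08. Plat rose 1.53-fold from 97.6 to 149 CPM (log2 0.61 ± 0.09, edgeR adjusted p = 0.00181) and Timp2 fell as above. The urokinase gene Plau fell 2.9-fold from 576 to 199 CPM (edgeR adjusted p = 0.0408), a call lost without each of the 6 libraries (0.0766 to 0.159). Integrins had 1 of 47 higher and 3 lower (1 and 4 adjusted over the list alone, camera adjusted p = 0.531). The lower count was 0, 1 and 1 without scrambled replicates 1, 2 and 3 and 0 without Esr2 siRNA replicate 1 or 3. Migration and guidance genes had 1 of 58 higher and 2 lower (3 and 3 adjusted over the list alone, 0.994), and 3 higher without Esr2 siRNA replicate 2. The semaphorin co-receptor gene Plxna2 fell 1.78-fold from 129 to 72.4 CPM. Structural matrix genes had 1 of 58 higher and 1 lower (1 and 1 adjusted over the list alone, 0.649), and 3 lower without Esr2 siRNA replicate 2. The collagen gene Col16a1 fell 2.07-fold. Junctions had 1 of 46 higher and 1 lower (1 and 2 adjusted over the list alone, 0.994), and actomyosin 0 of 37 higher and 1 lower (0 and 2, 0.2).

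Camera called 3 of 31 lists after Esr2 siRNA, 1 upward and 2 downward. Interferon response genes had a median log2 change of -0.75, yet 2 of 39 were called lower and 0 higher (24 and 0 adjusted over the list alone). The camera adjusted p was 4.5e-14, the adjusted p = 0.996 with an estimated correlation, and fry gave 0.244. The genes called were Trim25, 1.55-fold lower, and Bst2, 1.6-fold lower from 221 to 138 CPM. Trim25 was lost without scrambled replicate 1 (edgeR adjusted p = 0.0556) and Esr2 siRNA replicates 1 (0.0684) and 3 (0.0617). Bst2 was lost without scrambled replicates 1 to 3 or Esr2 siRNA replicate 1 or 3 (0.068 to 0.123). The list's score was -1.19, -0.30 and -1.21 in Esr2 siRNA replicates 1 to 3, and without replicate 2, 24 genes were called lower. Granulosa identity genes moved downward, with 0 of 24 higher and 1 lower (1 and 7 adjusted over the list alone, camera adjusted p = 0.0167; adjusted p = 0.178 with an estimated correlation). The call was lost without Esr2 siRNA replicate 2 (0.0726), and fry gave 0.00106. Cholesterol synthesis moved upward with 1 of 25 higher and 1 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.00602; adjusted p = 0.996 with an estimated correlation). Sc5d fell 2.02-fold from 260 to 129 CPM, against the list's direction. Oestrogen-responsive genes had 3 of 27 higher and 3 lower (3 and 4 adjusted over the list alone, camera adjusted p = 0.994). The higher count was 1 without scrambled replicate 1, 2 or 3 or Esr2 siRNA replicate 1 or 3. The lower count was 0, 0 and 1 without scrambled replicates 1, 2 and 3 and 0 without Esr2 siRNA replicate 1. The theca and stroma score was uneven within the groups, at -0.19, -0.88 and 0.39 after Esr2 siRNA and -0.79, 0.59 and 0.20 with scrambled siRNA, and 0 of its 17 genes were called.

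Esr2 siRNA changed 631 genes (4.2%), 168 higher and 463 lower. Of these 22 and 111 changed at least 2-fold, and 2625 genes had an unadjusted p under 0.05. The count was 342, 306 and 255 without scrambled replicates 1, 2 and 3 and 238, 1030 and 309 without Esr2 siRNA replicates 1, 2 and 3. It was 250 higher and 396 lower with upper-quartile scaling, 1131 when only the groups compared were fitted, 1098 with DESeq2 and 4731 with voom.

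**Figure D4:**
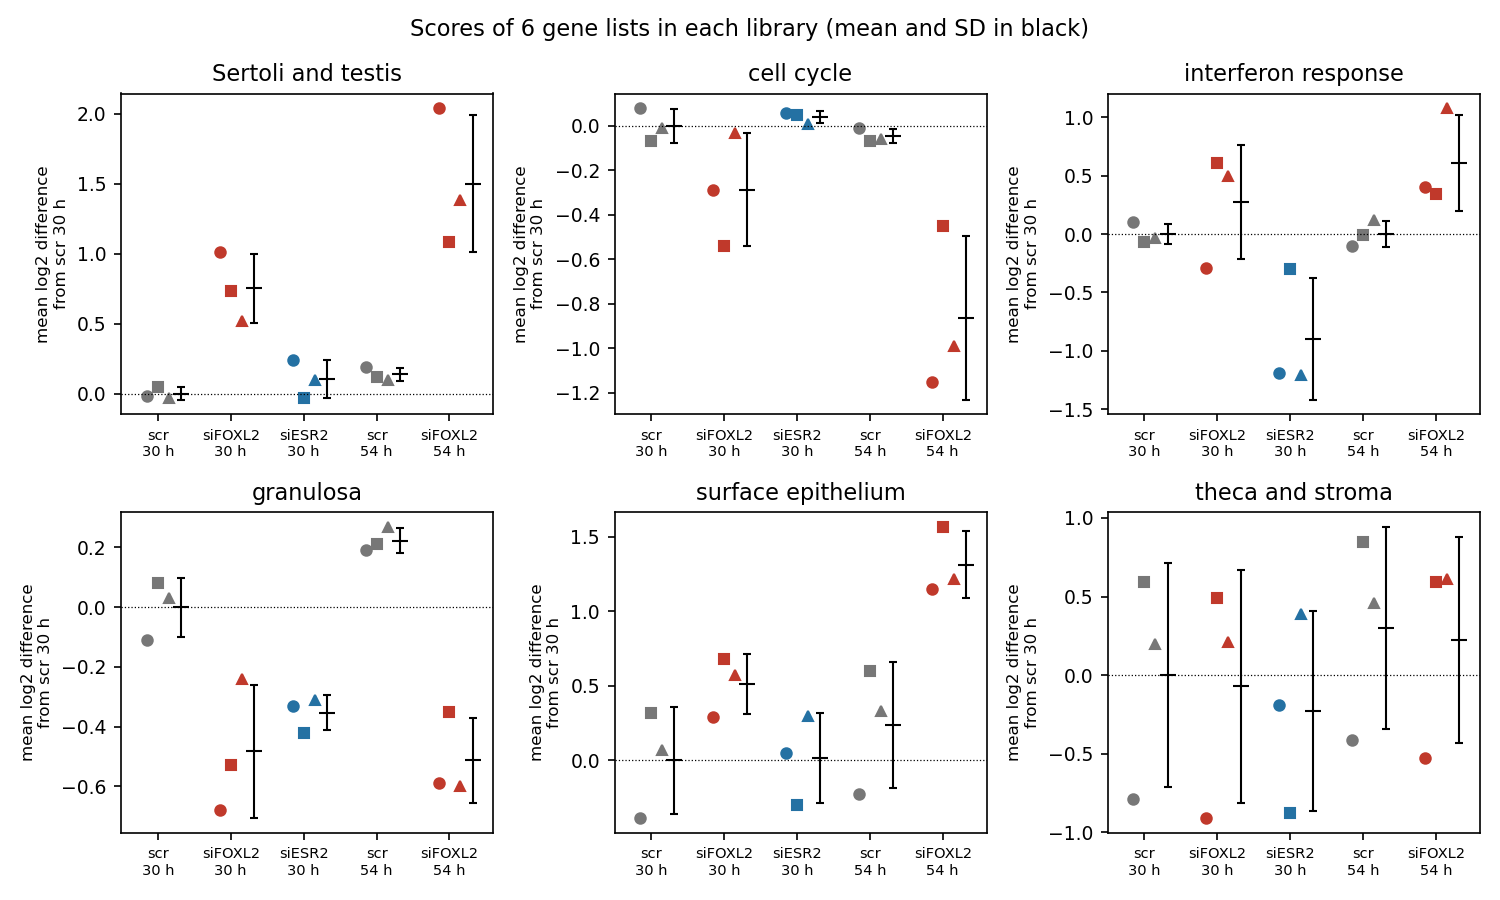
Score of 6 gene lists in each library (y axis, mean log2 difference from the scrambled libraries at 30 h) by group (x axis), with the mean and SD of 3 libraries in black. The Sertoli score was 0.75 ± 0.25 and 1.5 ± 0.49 after Foxl2 siRNA at 30 h and 54 h, the cell cycle score -0.29 ± 0.26 and -0.86 ± 0.37, and the interferon score -0.9 ± 0.52 after Esr2 siRNA.

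Both knockdowns at 30 h lowered Hsd11b2, Sc5d and Gpr165. In all, 30 genes were higher and 111 lower after both siRNAs, against 10.7 and 30.8 for independent lists. Another 64 moved in opposite directions, Plat among them, and no count for independent lists was made for opposite directions. Log2 changes correlated at 0.26 across genes, against a mean of 0.5 in simulations of unchanged groups sharing the scrambled libraries. The covariance was 0.0475 against 0.0371 in those simulations, a difference of 0.0104. Those simulations gave a mean of 0 shared calls and at most 1. No gene was changed in them, so they do not give the chance overlap of lists as long as the real ones. The 3 shared controls were too few to be split, and part of the excess may come from them. The shared total of 141 was 70, 58 and 44 without scrambled replicates 1, 2 and 3, and 56 and 71 without Esr2 siRNA replicates 1 and 3. It was 88, 92 and 215 without Foxl2 siRNA replicates 1, 2 and 3, and 250 with DESeq2. Foxl2 siRNA at 54 h, which has other control libraries, shared 55 higher and 186 lower genes with Esr2 siRNA, against 31 and 94.2 for independent lists. There 136 genes moved in opposite directions, and the correlation was 0.18.

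Compared directly at 30 h, Asb12 was 8.61-fold higher after Foxl2 than after Esr2 siRNA (log2 3.11 ± 0.20, edgeR adjusted p = 1.49e-06), and Pmp22 8.32-fold higher, at 50.2 against 6.03 CPM (log2 3.06 ± 0.22, edgeR adjusted p = 2.55e-06). Serpina3a was 12.9-fold, Mybpc3 5.68-fold and Mybphl by a log2 of 2.60 ± 0.50 higher. Rnf152 was 12.3-fold and Frem2 12.1-fold lower, and Slc7a8 7.23-fold lower, at 84 against 608 CPM. Asgr1 and Slc16a11 had log2 differences of -3.38 ± 0.36 and -3.39 ± 0.44, the latter -3.97 without Foxl2 siRNA replicate 3. Interferon genes were higher after Foxl2 siRNA, with 30 of 39 called higher and 0 lower (34 and 1 adjusted over the list alone) and a median of 1.02 (camera adjusted p = 1.52e-12). The interferon score was -0.29, 0.61 and 0.50 in Foxl2 siRNA replicates 1 to 3 and -1.19, -0.30 and -1.21 in Esr2 siRNA replicates 1 to 3, so Foxl2 siRNA replicate 1 lay level with Esr2 siRNA replicate 2. The count of 30 was 10 without Esr2 siRNA replicate 1 or 3 and 15 without Foxl2 siRNA replicate 2. Cell cycle genes were lower, 7 of 50 called (6 adjusted over the list alone, camera adjusted p = 2.87e-06). That count was 2 without Esr2 siRNA replicate 1 or 3, and 3, 2 and 18 without Foxl2 siRNA replicates 1, 2 and 3. Ovulation genes were lower, 12 of 27 with 2 higher (14 and 3 adjusted over the list alone, camera adjusted p = 0.000104). Sertoli genes were higher, 7 of 20 with 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.0352). The Sertoli call was lost without Esr2 siRNA replicates 2 (0.0732) and 3 (0.05) and Foxl2 siRNA replicates 1 (0.0801) and 2 (0.0507). Each of these 4 lists had an adjusted p = 0.891 with an estimated correlation. In all 3042 genes differed, 1649 higher and 1393 lower after Foxl2 siRNA. Foxl2 and Esr2 themselves differed by -1.47 ± 0.30 (edgeR adjusted p = 0.00435) and 1.27 ± 0.35 (0.0203). The Esr2 call was lost without Esr2 siRNA replicates 1 (0.077) and 3 (0.0609) and Foxl2 siRNA replicate 3 (0.0656). The count of genes was 1767 and 1998 without Esr2 siRNA replicates 1 and 3, 1625 when only the groups compared were fitted and 5446 with voom.

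Culture from 30 h to 54 h with scrambled siRNA changed 1 gene. Bcar1, the focal adhesion adaptor, fell from 211 to 156 CPM (log2 -0.44 ± 0.06, edgeR adjusted p = 0.0467), and 727 genes had an unadjusted p under 0.05. Cyr61, Cnn2 and Ankrd1, genes of contractile or stretched cells, had log2 changes of -0.69 ± 0.14, -0.55 ± 0.12 and -0.71 ± 0.17 that did not pass (edgeR adjusted p = 0.239, 0.239 and 0.345). Camera called 4 lists lower at 54 h: actomyosin (median -0.21, adjusted p = 4.96e-12), dissociation stress (-0.14, 0.00631), smooth muscle and pericyte (-0.47, 0.0196) and integrin genes (-0.07, 0.0196). Their members called lower numbered 0, 0, 0 and 1, and 6, 1, 0 and 1 adjusted over the list alone. The adjusted p was 0.173, 0.359, 0.947 and 0.947 with an estimated correlation, and fry called 0 lists. The stress call was lost without scrambled 30 h replicate 1 (0.0519). The integrin call was lost without 30 h replicates 2 (0.11) and 3 (0.0788) and 54 h replicate 1 (0.131), and the smooth muscle call without the same libraries (0.0912, 0.355 and 0.451). The count of 1 gene became 0 without any 1 of the 6 libraries, with DESeq2's size factors and with no filter on low counts. The main fit used no pairs. With the replicate number as a block, taken to pair the scrambled libraries of both times, 3 genes were called, 1 higher and 2 lower. In a blocked fit of the 6 scrambled libraries alone, chosen after seeing the data, 1586 genes were called, 896 higher and 690 lower, and 11 of 30 lists, 5 upward and 6 downward. Without the block, DESeq2 called 63 genes, voom 2693 and a fit of the 6 libraries 206.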

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

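The tests of exchanged labels and of an innate response to the siRNA, and all splits of the samples, were chosen after the results were seen; the other tests of this part were written down before their results.

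Foxl2 siRNA replicate 3 at 30 h and replicate 2 at 54 h stood closer to scrambled cells than their group-mates, with 65.4 and 57.5 CPM of Foxl2 and principal component 1 scores of 6.2 and 32.4. An exchange of the labels between the times, made after the spike-in RNA was added, is argued against by that RNA. The log2 ratio of ERCC-00130 to ERCC-00002 in either library lay within 0.07 of its group-mates while the groups stood at -2.27 and 0.855. An exchange made before that step could leave the ratio unchanged and stays open. Untransfected cells in both libraries cannot be told apart from a weaker knockdown: on a scale from 0 at their group-mates to 1 at scrambled cells, genes that rose lay at a median of 0.546 and 0.555, genes that fell at 0.291 and 0.381 and Foxl2 itself at 0.273 and 0.2, and rising and falling genes differed by 0.254 at most, against -0.235 to 0.0886 in the other 4 libraries. The data are consistent with 1 culture carrying number 3 at 30 h and number 2 at 54 h, since over 1563 genes that answered at neither time the deviations of these libraries correlated at 0.53, beside 0.77 for replicates 1 and 1, 0.68 for replicates 2 and 3 and -0.57 to -0.03 for the other 6 pairs. Whether such a culture took up less siRNA or held cells that answered less stays open.

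Interferon response genes had a median log2 change of -0.75 after Esr2 siRNA, with list scores of -1.19, -0.30 and -1.21 in replicates 1 to 3. A different content of theca and stroma cells as the whole cause is argued against by the fit with that marker score as a covariate, in which the median was -0.78 (camera adjusted p = 7.53e-12). A different innate response to the siRNA pools themselves may contribute and cannot be told apart from an effect of Esr2: after Foxl2 siRNA the median was 0.33 against the same scrambled libraries, and no untransfected library was analysed here. A biological effect of lower Esr2 stays open as well, as a hypothesis that the design confounds with the pool.

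Gadd45b was the 1 gene whose answer to Foxl2 siRNA differed between the times by the test of the difference, by 1.09 ± 0.12 on the log2 scale (edgeR adjusted p = 0.00778). Lower levels with scrambled siRNA at 54 h than at 30 h made up part of this difference. That test used no pairing of libraries across the times. Krt19 and Tpm1, of 188 named genes, were picked out because all 3 Foxl2 siRNA libraries lay below the mean of the scrambled ones at 30 h and all 3 above it at 54 h. Their changes differed by 0.65 and 0.46 on the log2 scale, and neither difference passed the test (edgeR adjusted p = 0.513 and 0.2).

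The spike-in RNA, which entered no comparison, split the groups along neither treatment alone nor time alone. Within each time it set scrambled siRNA apart from targeted siRNA, in opposite directions at 30 h and 54 h, and the cause was not tested. The log2 ratio of ERCC-00130 to ERCC-00002 was 0.719 ± 0.051 with scrambled siRNA at 30 h, 0.855 ± 0.05 with Foxl2 siRNA at 54 h, -2.19 ± 0.022 with scrambled siRNA at 54 h, -2.21 ± 0.064 with Esr2 siRNA and -2.27 ± 0.04 with Foxl2 siRNA at 30 h (SD, n = 3). The difference from the scrambled libraries of the same time was -2.99 for Foxl2 siRNA at 30 h, 3.04 for Foxl2 siRNA at 54 h and -2.93 for Esr2 siRNA.

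Other splits of the 6 libraries of a comparison number 10 with the real one, too few for a share under 0.05. The real split called 1936 genes for Foxl2 siRNA at 30 h, 5787 at 54 h, 631 for Esr2 siRNA, 3042 between the siRNAs and 1 between the scrambled times, the highest other split called 0 in each case, and 1 split was as large, the real one. Every other split puts libraries of both real groups on each side, so a true difference between the groups adds to the spread and lowers the count. The 0 calls therefore do not measure what chance gives. For gene lists the real and the highest other counts were 7 and 15 for Foxl2 siRNA at 30 h, 13 and 14 at 54 h, 3 and 17 for Esr2 siRNA and 4 and 17 between the scrambled times, with 7, 4, 5 and 7 splits as large. In each comparison some mixed split thus called more lists than the real one. The number of lists that camera called therefore does not set the real groups apart from mixed ones. The difference between the Foxl2 siRNA answers at the 2 times was fitted without pairing libraries across the times. Chance could not be excluded for it: 7 of 100 splits called at least the real count of 1 gene. The highest other split called 4750 genes, which points to a structure of the samples. The Foxl2 siRNA change itself can be that structure. Libraries were regrouped within each time separately, so a split can turn this change into a difference between the times. The splits therefore cannot decide about chance.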

How the results depend on the processing

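The fit with the theca and stroma covariate, that of the scrambled libraries alone with the block, leaving out 1 library and the block for the lists of the direct contrasts, and that without both libraries that kept the most Foxl2 were chosen after the data were seen, and the cause of a change was not tested except where fewer libraries or a harder threshold made it. No result reversed. With DESeq2's size factors or no filter on low counts 0 genes changed between the scrambled times, and all other counts of genes stayed within 1.5 times. DESeq2 called 1098 genes for Esr2 siRNA, 63 between the scrambled times, 199 for the difference between the Foxl2 siRNA answers and 250 shared by both siRNAs. Voom called 5252 genes for Foxl2 siRNA at 30 h, 4731 for Esr2 siRNA, 2693 between the scrambled times, 1056 for the difference of answers and 5446 between the siRNAs. Fitting only the groups compared gave 1131 for Esr2 siRNA, 206 between the scrambled times and 1625 between the siRNAs. With a 2-fold minimum the counts were 504 and 1530 for Foxl2 siRNA at 30 h and 54 h, 133 for Esr2 siRNA, 0 between the scrambled times and 673 between the siRNAs, and at an adjusted p under 0.01 they were 769, 3707, 252, 0 and 1496. The covariate gave 12 genes between the scrambled times and 40 for the difference of answers, and leaving out both libraries that kept the most Foxl2 gave 836. Leaving out 1 library in turn gave 898 to 3016 genes for Foxl2 siRNA at 30 h, 4424 to 6752 at 54 h, 238 to 1030 for Esr2 siRNA, 0 in each case between the scrambled times, 1 to 904 for the difference of answers and 1767 to 3647 between the siRNAs. It gave 44 to 215 genes shared by both siRNAs and 881 to 2631 shared by both times. Lists called were then 4 to 7 for Foxl2 siRNA at 30 h, 9 to 15 at 54 h, 2 to 4 for Esr2 siRNA and 2 to 6 between the scrambled times. With an estimated correlation 0 lists were called in each of these comparisons, and fry called 3, 17, 1 and 0. The replicate block gave 3 genes between the scrambled times, whose numbers were taken as pairs, and the block of the 6 scrambled libraries alone 1586 genes and 11 lists. In the other comparisons the libraries share only a number: correlations for numbers 1 to 3 were 0.49, 0.44 and 0.07 for Foxl2 siRNA with scrambled siRNA at 30 h, 0.40, 0.02 and 0.14 at 54 h and -0.14, -0.47 and 0.32 for Esr2 siRNA, and 0.66, -0.26 and -0.29 for Foxl2 siRNA at both times. There the block gave 1904, 5754 and 607 genes for Foxl2 siRNA at 30 h and 54 h and Esr2 siRNA, 3012 between the siRNAs and 1 for the difference of answers. Of the named genes it ended the call of Nat8l after Foxl2 siRNA at 30 h (edgeR adjusted p = 0.0626) and, after Esr2 siRNA, those of Cbs (0.0545), Plau (0.0656), Bcar1 (0.0571), Por (0.0604) and Neurl1a (0.0626), an uncertain gene. The block ended no list call of the 4 comparisons with camera counts, none of the 6 list calls described for the direct contrasts, and no other call of a named gene. The stricter filter left Amh, Fshr, Lhcgr, Adamts20 and Rgs5 without a value, and DESeq2 gave no adjusted p for Grem1 after Foxl2 siRNA and Cbs after Esr2 siRNA. Over 4420 pairs of a named gene's result and a setting 4089 stayed on their side of the threshold, 185 lost the call, 165 of them when a library was left out, 146 gained one and 0 reversed. Depth limits the genes near the floor of 0.0504 to 0.0667 CPM, such as Cyp19a1 after Foxl2 siRNA at 54 h with 9 counts in 3 libraries, and the intervals of such ratios cover counting error only.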

Other observations

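All gene groups of this part were chosen after the values were seen, as was the test of S phase; the tests of shared reads and of RNA without a poly(A) tail were written down before their results. Foxl2 siRNA raised genes of the sarcomere and of muscle calcium handling, 7 of 28 at 30 h with 1 lower (camera adjusted p = 0.000164; adjusted p = 0.0299 with an estimated correlation) and 14 at 54 h with 2 lower (camera adjusted p = 7.68e-06; adjusted p = 0.0113 with an estimated correlation). Medians of the log2 change were 0.66 and 1.26. Ldb3, a Z-disc protein gene, rose by 1.24 ± 0.26 and 2.19 ± 0.27 on the log2 scale at 30 h and 54 h, and Smpx by 2.88 ± 0.22 at 54 h. At 54 h the troponin genes Tnnt1 and Tnnc1 rose by 2.65 ± 0.42 and 0.89 ± 0.18, while Neb, which encodes nebulin, fell by 1.02 ± 0.15. After Esr2 siRNA 0 were higher and 2 lower, Neb and Tnnc1, with log2 changes of -0.87 ± 0.14 and -1.40 ± 0.19.

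Of 10 claudin genes, which encode tight junction proteins, 7 were higher and 1 lower at 54 h (camera adjusted p = 0.0168; adjusted p = 0.192 with an estimated correlation). Cldn11 and Cldn6 rose by 2.62 ± 0.51 and 2.25 ± 0.32 on the log2 scale. The surface epithelium markers, which include the claudin gene Cldn15, moved upward in the same group. Glutathione transferase genes had 8 of 20 higher and 1 lower (camera adjusted p = 0.00267; adjusted p = 0.45 with an estimated correlation), and serpin genes 14 of 36 higher and 3 lower (0.00267; adjusted p = 0.599 with an estimated correlation). Mitochondrial ribosomal protein genes had 1 of 77 higher and 26 lower (camera adjusted p = 0.000343; adjusted p = 0.753 with an estimated correlation). In all 24 such groups were looked at.

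Histone genes rose after Foxl2 siRNA at 54 h, 44 of 54 with 0 lower and a median log2 change of 1.03 (camera adjusted p = 6.17e-11; adjusted p = 0.45 with an estimated correlation), and their summed level was 651, 371 and 652 CPM in replicates 1 to 3 against 302 ± 11.8 CPM with scrambled siRNA (SD, n = 3). Reads shared between histone genes as the cause are argued against by the 6 that share under 10% of their 75-base words with other genes: all 6 were higher, among them Hist2h2be and Hist1h1b (log2 0.68 ± 0.14 and 1.15 ± 0.26), with a median of 0.96. More cells in S phase are argued against by the cell cycle list, whose median was -0.76 in the same comparison. Capture of RNA without a poly(A) tail may play a part and stays open: 76 other small RNAs of that kind had a median of -0.29, under the bound of 0.3 written beforehand, but 70 lie inside a longer gene whose transcript can add to their counts. The other 6, set apart after the values were seen, had a median of 0.17 with an SD of 1.03 and 0 called. They ran from -0.16 ± 0.21 for Snord104 to 2.43 ± 1.27 for Rmrp, so they did not lie under the bound by more than their spread. Apart from more cells in S phase, no biological explanation was tested.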
